A study of Arabidopsis thaliana with 4 samples.

How the data were processed

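Transcripts were measured by RNA sequencing in whole 10-day-old seedlings of Arabidopsis thaliana, ecotype Col-0. There were 2 groups: wild type (WT), and plants labelled as carrying both the bak1-4 and the serk4-1 alleles, called here the labelled double mutant. Each group had 2 libraries, numbered replicate 1 and replicate 2 in the labels. Per the series design text, every library was built from RNA of 2 biological replicates mixed in equal amounts, and sequenced as single-end reads on an Illumina HiSeq instrument. Per the labels' protocols, the plants grew on agar plates with sucrose at 23 °C with 12 h of light, stood overnight in 2 ml of water before harvest, and the libraries were made with a TruSeq kit. The spread between libraries is therefore the spread between pools, and the p-values do not measure the spread within a pool. The main fit has no term for the replicate number. Its p-values therefore also take in any difference shared by libraries of the same number, and such a difference is described below.

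The submitters' processing notes list bcl2fastq 1.8.4, cutadapt 1.0, TopHat2 2.0.12, HTSeq 0.5.4 and DESeq 1.12.0 and the build TAIR10. Their roles, settings and annotation version are not given in the sources used here, nor is whether counting used the strand. Values of overlapping genes, of genes with an antisense partner and of near-identical gene copies are uncertain for that reason.

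The deposited values are a normalised signal: per the file headers the column is a base mean, the word DESeq uses for read counts divided by a size factor. Each library listed 33278 loci. Each value was divided by the smallest nonzero value of its library, and 100% of the values came out whole within 0.001 in every library, which recovered the reads per gene behind the deposited signal. The recovered reads totalled 17818007 and 20081599 in the WT libraries and 16662650 and 7414741 in the labelled double mutant libraries. Depth was thus lowest in labelled double mutant replicate 2. Counting intervals and floors cover counting error only, because the libraries carry no molecular identifiers. The files held 0 chloroplast or mitochondrial loci, so library totals are of nuclear genes.

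Locus identifiers were used as the files give them. Of the 33278 identifiers, 32810 matched the reference annotation of assembly TAIR10.1, which supplied symbols for 10647, product names, the order of neighbouring genes and spliced sequences. Its name differs from that of the build in the notes, so no coordinates are given. Of the 336 members of the gene lists, 326 carry the list's symbol in the reference. The others are called by the reference's symbol or by their locus. The reference gives the symbol DAD1 to another gene, and the oligosaccharyltransferase subunit AT1G32210 was kept under the name ATDAD1.

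The groups, the tests, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The plan assumed whole-number counts tested with edgeR and set limma as the test for normalised values. Because the deposited values are normalised, the main test was limma 3.58.1 (trend, R 4.3.3) on log2(value + 1), with genotype as the term, over genes with a mean value of at least 1. Fold changes are on that scale, which understates the change of genes with low values in both libraries of a group. Where only 1 library of a group has 0 reads, the fold change can instead be larger than that of edgeR. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. All adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment unless another tool is named. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads (TMM scaling), limma after TMM scaling, and limma after thinning were alternatives chosen after the files were seen.

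A fold against a group with 0 reads was computed against a floor of 3 reads over the group and is given as a lower bound. With 1 to 3 reads in a group, the ratio of pooled reads is given with its 95% counting interval. Lists of genes were tested with camera in limma with a preset correlation of 0.01, adjusted over the 21 lists, again with the correlation estimated from the data, and with fry. With an estimated correlation, camera takes its degrees of freedom from the few libraries rather than from the genes. That form can hardly call a list after adjustment, even at a low correlation. Members were also counted after adjustment over the list alone. Families were formed from the reference's product names and tested with camera where at least 10 members were measured.

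Named genes were the 5 SERK genes, and, among genes with an adjusted p below 0.05, a mean CPM of at least 5 and both labelled double mutant libraries on the same side of both WT libraries, the 8 with the highest and the 8 with the lowest log2 fold change. From each list the rule took the 2 members with the largest change in the direction most passing members took and the 1 with the largest change the other way. Where no member passed, it took the member with the highest mean as a value only. The rule gave 57 genes. Any other gene is said to be chosen after its values were seen.

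Replicates were compared with a chi-square test of reads over genes. Chi-square was 53.9 times its degrees of freedom for the WT pair and 76.2 times for the labelled double mutant pair, above sampling noise, so neither pair looks like a library deposited under both numbers. This does not show that the pools were separate. The libraries were counted separately because the series design text calls the repeats independent. Both tests were tested on simulated reads for 2 against 2 libraries over 20510 genes, 200 of them changed. Of the genes changed 2-fold, limma recovered 0%. It recovered 40% of those changed 4-fold, 98% of those changed 16-fold and 100% of those changed 64-fold, and 8 of its 127 calls were genes left as they were. For edgeR the shares were 0%, 42%, 98% and 100%, and 18 of its 138 calls were such genes. With 4145 genes changed, 158 of 3538 limma calls and 172 of 3576 edgeR calls were. With no gene changed, each test called 1 gene. With the 21 jasmonate genes simulated at a 4-fold rise, camera ranked that list 1 of 21, while limma and edgeR each called 0 of its members. Simulated genes varied independently of each other, so camera with the preset correlation was not tried on correlated genes. Simulated libraries varied independently too, with no difference shared by libraries of the same number. The shares recovered and falsely called may therefore not hold for the real libraries.

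Alternatives were other scalings (RLE factors, library size only), DESeq2 1.42.0 and edgeR on recovered reads, a robust prior, no filter, a stricter filter of a CPM of 5 in 2 libraries, pseudocounts of 0.1 and 5, the replicate number as a block, and each library left out. To count transcript stretches shared between loci, all 50-base windows of the SERK transcripts were matched to the reference transcripts with bwa 0.7.19, allowing 2 mismatches.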

Results

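Transcript levels were compared between WT seedlings and seedlings labelled bak1-4/serk4-1. BAK1 and SERK4 are related leucine-rich repeat receptor kinases that act as co-receptors in brassinosteroid and immune signalling, and the series concerns the cell death these kinases restrain and its link to protein glycosylation. Reads were counted at 22886 and 23177 loci in the WT libraries and at 22701 and 22026 in the labelled double mutant libraries. Across genes, log2 values correlated with r = 0.966 between the WT libraries and r = 0.942 between the labelled double mutant libraries, against 0.775 to 0.840 between groups. Genes are not independent replicates in these correlations.

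The first question was whether the targeted genes were lower in the libraries labelled as mutant. BAK1 (AT4G33430, chromosome 4) was not. Its normalised read counts were 1057 and 832 in WT and 994 and 881 in the labelled double mutant, and the log2 fold change was -0.00 (SE 0.28, limma adjusted p = 0.997). SERK4 (AT2G13790, chromosome 2) had 227 and 260 in WT and 319 and 558 in the labelled double mutant, a log2 fold change of 0.79 that did not pass (SE 0.36, limma adjusted p = 0.190). SERK2 (AT1G34210) fell from 521 and 649 in WT to 204 and 169 (log2 fold change -1.64, SE 0.29, limma adjusted p = 0.0204). SERK5 (AT2G13800), the neighbour of SERK4, rose from 128 ± 18.4 to 304 ± 37.7 (SD, n = 2 libraries per group; log2 fold change 1.25, SE 0.31, limma adjusted p = 0.0462). SERK1 (AT1G71830) had a log2 fold change of -0.90 (SE 0.32) and did not pass. Of the 5 SERK genes, 1 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.857). Counts over a whole gene do not show where in the gene reads fall, so they can neither support nor exclude the labels, and every direction below is that of the libraries labelled double mutant. Values of SERK4 and SERK5 are uncertain because 35.1% of the 50-base windows of SERK4 and 37.4% of those of SERK5 matched another locus. The SERK5 call was lost with TMM factors (limma adjusted p = 0.0506) and with library size only (0.0545), and the SERK2 and SERK5 calls were lost in limma without any 1 of the 4 libraries.

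**Figure D1:**
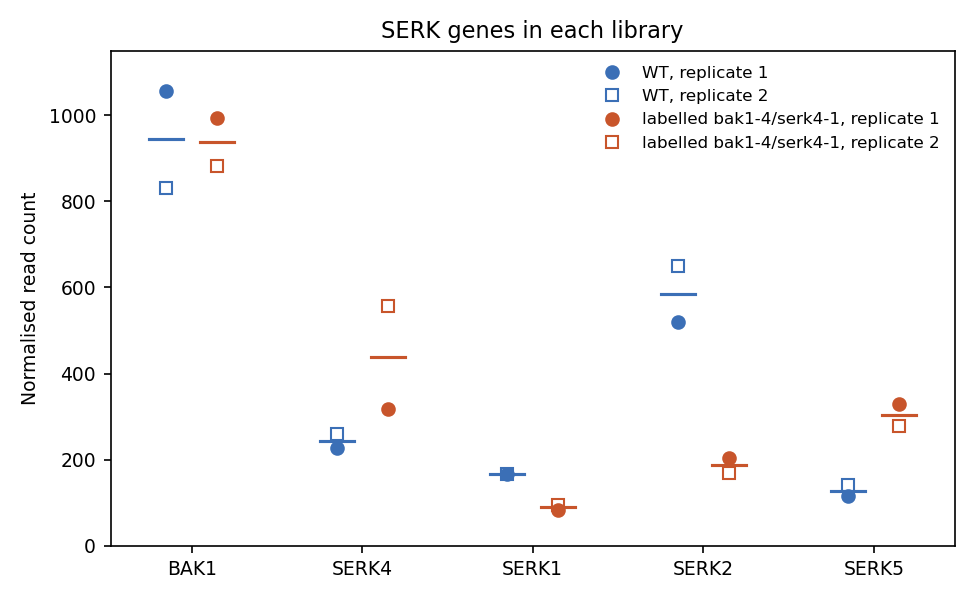
Normalised read counts (vertical axis, starting at 0) of the 5 SERK genes in each of the 4 libraries; filled circles are replicate 1, open squares replicate 2, and bars the mean of each group. BAK1 lies at 944 ± 159 in WT and 938 ± 79.5 in the labelled double mutant (SD, n = 2), while SERK2 lies at 521 and 649 in WT and at 204 and 169 in the labelled double mutant.

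The next comparison asked which genes differed between the groups across the genome. Among the genes with the highest rises were several known from pathogen defence. PR1 (AT2G14610), a pathogenesis-related protein widely used as a marker of the salicylic acid response, rose from 6.27 ± 5.02 in WT to 70716 ± 23449 in the labelled double mutant (SD, n = 2; log2 fold change 13.40, SE 0.57). It took 0.541% and 0.406% of all reads there. PR2 (AT3G57260), a beta-1,3-glucanase, rose from 3.75 ± 0.491 to 13777 ± 7599. PCR1 (AT1G14880), of the plant cadmium resistance family, rose from 2.18 ± 0.765 to 27388 ± 10300, and LURP1 (AT2G14560) from 15.1 ± 21.4 to 13497 ± 3336. CYP82C2 (AT4G31970), a cytochrome P450, had 0 reads in both WT libraries and normalised counts of 15712 and 3121 in the labelled double mutant, where pooled reads were at least 10150-fold higher, and at least 2802-fold higher without replicate 1. AT2G44240, a DUF239 protein, and AT1G33950, of the avirulence-induced AIG1 family, likewise had 0 reads in WT and were at least 2274-fold and 1327-fold higher. Their bounds were 3623-fold and 1847-fold without labelled double mutant replicate 1, and 1548-fold and 1046-fold without replicate 2. Without WT replicate 1 and without WT replicate 2, where the floor covers fewer reads, the bounds were 5545-fold and 4604-fold for CYP82C2, 1243-fold and 1032-fold for AT2G44240, and 725-fold and 602-fold for AT1G33950. The wall-associated kinase gene WAK3 (AT1G21240) had 2741 and 2734 against 1.64 and 0 in WT, a ratio of 3688 with a 95% counting interval of 1020 to 30460.

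The genes with the deepest falls encode proteins of different kinds. A thionin gene, AT1G66100, fell from 4419 ± 1208 to 17.0 ± 24.0 (SD, n = 2; log2 fold change -9.52, SE 1.60), and a second, THI2.2 (AT5G36910), fell from 1164 ± 455 to 1.94 ± 2.74. FBA5 (AT4G26530), an aldolase, fell from 2406 ± 420 to 9.69 ± 13.7. MLP28 (AT1G70830) fell from 2078 ± 791 to 22.8 ± 32.2, GER3 (AT5G20630), a germin, from 1413 ± 636 to 9.13 ± 10.4, and the lipid-transfer family gene AT5G48490 from 1032 ± 109 to 13.1 ± 18.5. The glutaredoxin gene AT2G47880 had 295 and 270 in WT against 0.969 and 0 in the labelled double mutant, a ratio of 0.00224 with a 95% counting interval of 5.66e-05 to 0.0125. AT5G33370, of the GDSL lipase family, had 0 reads in the labelled double mutant and was at least 78.0-fold lower, with a bound of 27.3-fold without labelled double mutant replicate 1 and 50.7-fold without replicate 2. AT1G66100, THI2.2, FBA5, MLP28 and AT5G48490 had 0 reads in labelled double mutant replicate 2, the shallowest library. In replicate 1 their values were 33.9, 3.87, 19.4, 45.5 and 26.2, in that order. The size of these falls thus depends on the 1 added before the logarithm. By edgeR their log2 fold changes were -7.88, -8.86, -7.75, -6.38 and -6.12, against -9.52, -8.99, -9.05, -8.20 and -7.63 by limma. The falls of AT1G66100, MLP28 and AT5G48490 did not pass with a pseudocount of 0.1 (limma adjusted p = 0.0534, 0.0785 and 0.0728).

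In all, limma tested 22587 genes and called 4268 (18.9%), of which 2268 were higher and 2000 lower in the labelled double mutant. All 4268 differed at least 2-fold, which also reflects the power of the test: of simulated 2-fold changes limma recovered 0%. At an unadjusted p below 0.05 there were 7903. On the recovered reads edgeR called 4236 of 20510 genes, 2232 higher and 2004 lower, and 4061 genes were called by both tools in the same direction. The count rested on which libraries were kept. With WT replicate 1 or WT replicate 2 left out, limma called 0 genes, with 4047 and 4103 at an unadjusted p below 0.05, while edgeR called 3123 and 3226; without labelled double mutant replicate 1 and without replicate 2, limma called 1998 and 1410 and edgeR 4903 and 4302. With either WT library left out, the 52 named genes that limma had called were no longer called. That was so for 14 named genes without labelled double mutant replicate 1 and for 15 without replicate 2.

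**Figure D2:**
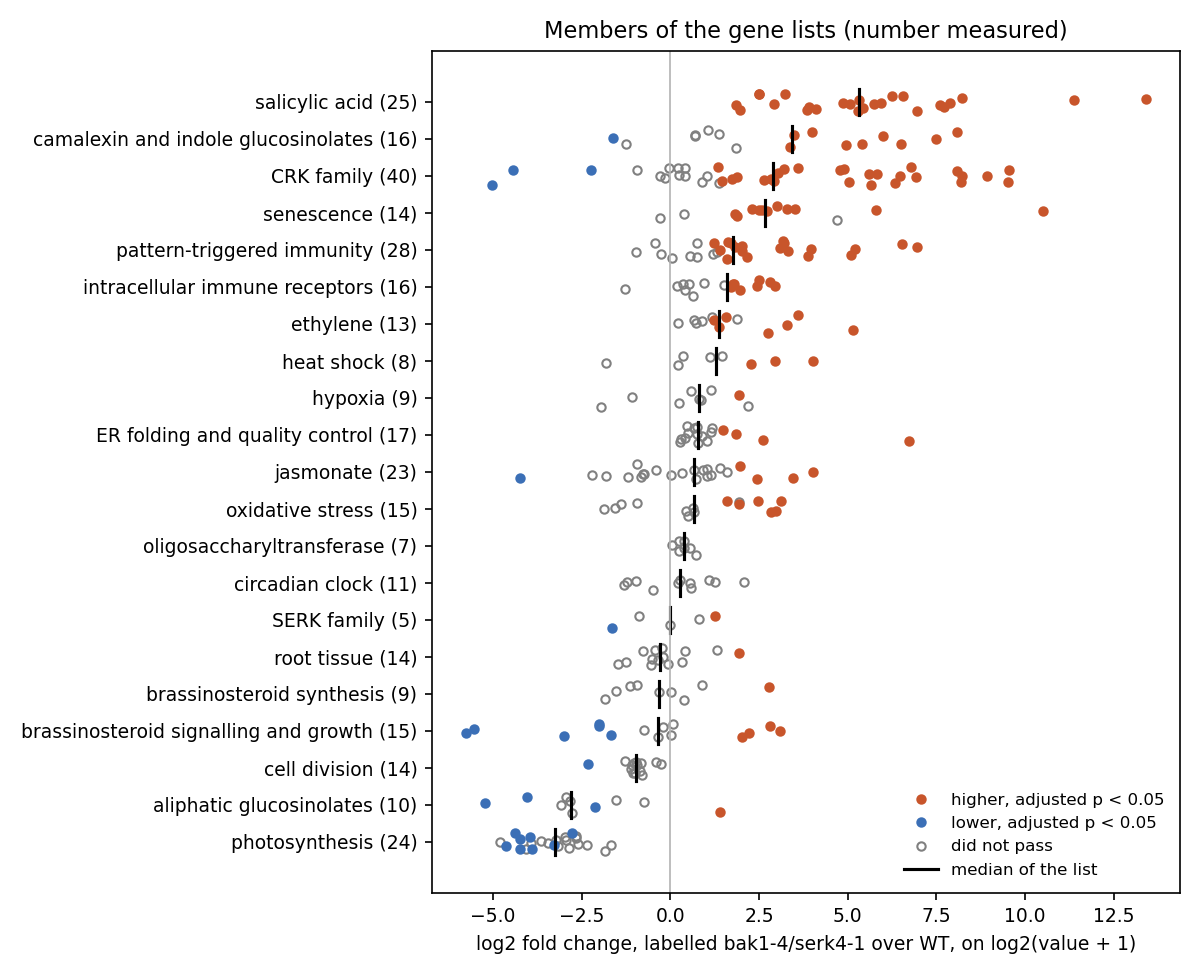
Log2 fold change of each measured member of the 21 gene lists, on log2(value + 1), in the labelled double mutant over WT (2 libraries each); filled points passed limma with Benjamini-Hochberg adjustment, open points did not, and black bars mark list medians. All 25 salicylic acid genes lie above 0, with a median of 5.33, and all 24 photosynthesis genes lie below 0, with a median of -3.26.

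Genes of salicylic acid and N-hydroxypipecolic acid synthesis and response rose together. All 25 measured members rose, also when adjusted over the list alone, with a median log2 fold change of 5.33 and a range of 1.85 to 13.40. The list took 0.0259% of reads in each WT library and 1.197% and 1.08% in the labelled double mutant libraries. Among members chosen after their values were seen, ICS1 (AT1G74710), which makes the precursor of salicylic acid, had a log2 fold change of 3.85 (SE 0.28), the transcription factor gene SARD1 (AT1G73805) 7.89 (SE 0.34) and FMO1 (AT1G19250), which makes N-hydroxypipecolic acid, 8.23 (SE 0.72). Of the 28 genes of pattern-triggered immunity, 19 rose, 0 fell and 9 did not pass, and 20 rose when adjusted over the list alone. MPK11 (AT1G01560), a MAP kinase, rose from 7.83 ± 0.501 to 1102 ± 138 (SD, n = 2), and FRK1 (AT2G19190), a receptor kinase gene induced by bacterial flagellin, from 23.6 ± 8.34 to 2321 ± 1120. The flagellin receptor gene FLS2 (AT5G46330), chosen after its values were seen, had a log2 fold change of 0.05 (SE 0.31) and did not pass. Of 16 intracellular immune receptors and partners, 8 rose and 0 fell, and 10 rose and 1 fell when adjusted over the list alone. The helper receptor ADR1 (AT1G33560) rose from 192 ± 63.5 to 1446 ± 249, and ZAR1 (AT3G50950) from 722 ± 83.4 to 4089 ± 202.

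The salicylic acid, pattern-triggered immunity and intracellular receptor lists passed camera with the preset correlation (adjusted p = 3.63e-21, 6.71e-10 and 1.28e-04). With an estimated correlation the adjusted p was 0.225, 0.225 and 0.361. When WT replicate 1 or WT replicate 2 was left out, limma called 0 members of these lists, while at an unadjusted p below 0.05 there were 25 and 25 salicylic acid, 18 and 20 pattern-triggered immunity and 7 and 9 intracellular receptor genes, and edgeR called 24 and 25, 12 and 14, and 4 and 4. Without labelled double mutant replicate 1 and without replicate 2, limma called 19 and 21, 7 and 7, and 3 and 4.

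Cysteine-rich receptor-like kinases (CRKs), a plant family of plasma membrane kinases with an extracellular domain rich in cysteine, were mostly higher in the labelled double mutant. Of 40 measured members, 26 rose, 3 fell and 11 did not pass; the median log2 fold change was 2.88, also with the 3 members at 0 reads in a group set to their bounds. When adjusted over the list alone, 28 rose and 3 fell. The study itself takes up this family, so its count is not independent evidence of a direction. CRK37 (AT4G04500) had 872 and 1937 in the labelled double mutant against 0.818 and 0.680 in WT, a ratio of 1676 with a 95% counting interval of 463 to 13850. CRK7 (AT4G23150) had 1186 and 1353 against 0 and 2.04, a ratio of 1117 with an interval of 382 to 5420. CRK30 (AT4G11460) fell from 185 ± 40.0 to 4.64 ± 1.08 (SD, n = 2; log2 fold change -5.04, SE 0.45). The other genes that fell, CRK42 (-4.44, SE 0.58) and CRK21 (-2.23, SE 0.38), were chosen after their values were seen. The list passed camera (adjusted p = 1.37e-10), and the adjusted p was 0.225 with an estimated correlation. Many CRK genes are close copies, so the split of reads among them is uncertain. After WT replicate 1 or WT replicate 2 was left out, limma called 0 members, with 24 and 25 higher and 3 and 3 lower at an unadjusted p below 0.05 and 21 and 23 higher by edgeR; without labelled double mutant replicate 2, it called 17 higher.

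**Figure D3:**
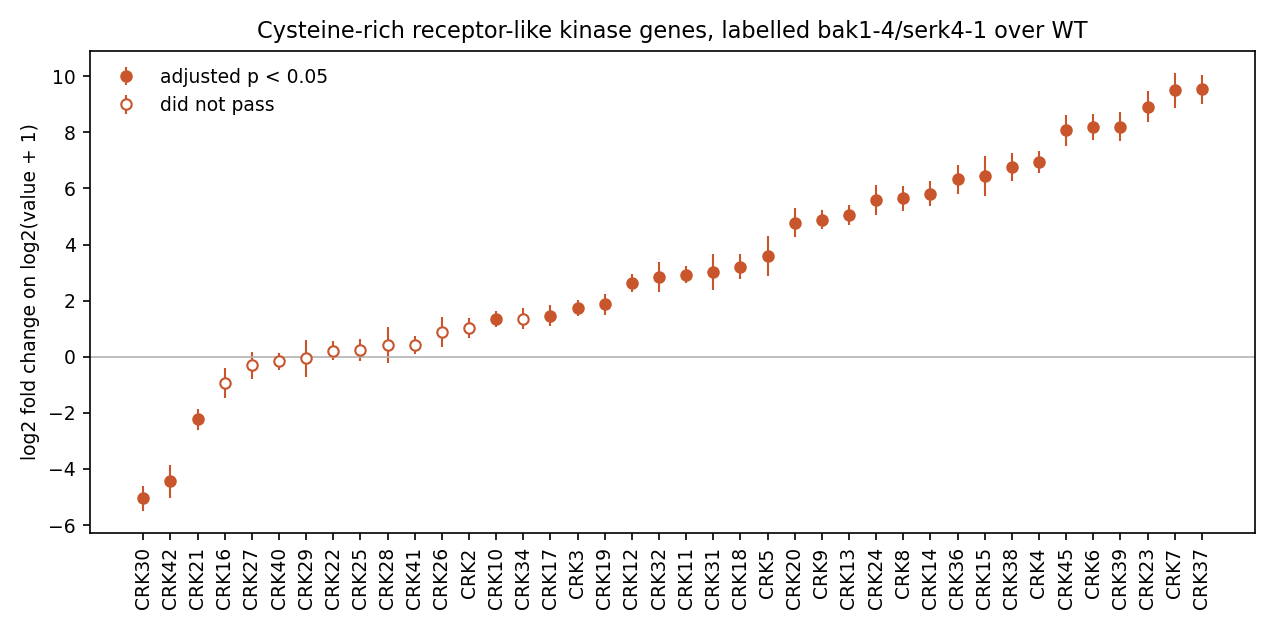
Log2 fold change on log2(value + 1) of the 40 measured CRK genes in the labelled double mutant over WT (2 libraries each), ordered by size; error bars are the standard error from limma, and filled points passed at an adjusted p below 0.05. Values run from -5.04 for CRK30 to 9.54 for CRK37.

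Ethylene genes that passed all rose, and the jasmonate genes that passed went both ways. Of 13 ethylene genes, 7 rose and 0 fell, and 8 rose when adjusted over the list alone. ACS2 (AT1G01480) and ACS6 (AT4G11280), which encode enzymes that make the precursor of ethylene, rose from 18.5 ± 15.5 to 609 ± 288 and from 126 ± 34.4 to 1227 ± 314 (SD, n = 2). Of 23 jasmonate genes, 4 rose, 1 fell and 18 did not pass, and 4 rose and 3 fell when adjusted over the list alone. The lipoxygenase gene LOX4 (AT1G72520) rose from 29.8 ± 3.97 to 496 ± 12.9 and JAZ7 (AT2G34600), a repressor of jasmonate signalling, from 13.1 ± 10.4 to 146 ± 90.6, whereas CORI3 (AT4G23600) fell from 148 ± 94.0 to 6.09 ± 0.979. The ethylene list passed camera (adjusted p = 1.48e-05, and 0.353 with an estimated correlation), and the jasmonate list did not (adjusted p = 0.374). With library size only, JAZ7 did not pass (limma adjusted p = 0.0501). Without WT replicate 1 and without WT replicate 2, limma called 0 members of both lists, with 6 and 7 ethylene and 5 and 3 jasmonate genes higher at an unadjusted p below 0.05 and 4 and 5, and 4 and 3, by edgeR; without labelled double mutant replicate 1 and without replicate 2 it called 3 and 3 ethylene and 2 and 1 jasmonate genes higher and no longer called CORI3.

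Of the genes for defence compounds made from tryptophan more rose than fell, and of those for glucosinolates made from methionine more fell than rose. Of 16 camalexin and indole glucosinolate genes, 9 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone. CYP71A12 (AT2G30750) and CYP71A13 (AT2G30770), which act in camalexin synthesis, rose from 29.4 ± 24.3 to 7446 ± 4336 and from 16.6 ± 13.1 to 2718 ± 435 (SD, n = 2); they are close copies and share reads uncertainly. MYB34 (AT5G60890), a regulator of indole glucosinolates, fell from 586 ± 33.7 to 190 ± 16.6. Of 10 aliphatic glucosinolate genes, 3 fell and 1 rose, and 4 fell and 1 rose when adjusted over the list alone. MYB28 (AT5G61420), a main regulator of this branch, fell from 1023 ± 60.7 to 72.4 ± 56.6 and BCAT4 (AT3G19710), which starts methionine chain elongation, from 659 ± 43.3 to 169 ± 115, whereas the sulfotransferase gene SOT17 (AT1G18590) rose from 279 ± 76.5 to 744 ± 205. Both lists passed camera (adjusted p = 1.22e-06 and 0.00521), with an adjusted p of 0.365 and 0.582 with an estimated correlation. BCAT4 did not pass in edgeR with TMM or RLE factors (edgeR adjusted p = 0.0508 and 0.0519), nor SOT17 with TMM factors or a robust prior (limma adjusted p = 0.0504 and 0.0509), nor either with a pseudocount of 0.1 (0.0590 and 0.0567). With WT replicate 1 or WT replicate 2 left out, limma called 0 members of both lists, with 9 and 8 indolic genes higher and 2 and 2 aliphatic genes lower at an unadjusted p below 0.05 and 9 and 9, and 5 and 6, by edgeR; without labelled double mutant replicate 1 and without replicate 2, it called 6 and 2 aliphatic genes lower, and MYB34 and SOT17 in neither.

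Photosynthesis genes were lower in the labelled double mutant. All 24 measured members, which encode light-harvesting proteins, Rubisco small subunits and Calvin cycle enzymes, had negative log2 fold changes, from -4.80 to -1.67 with a median of -3.26; 8 fell by limma over all genes and 23 when adjusted over the list alone. The Rubisco small subunit genes RBCS2B (AT5G38420) and RBCS1B (AT5G38430), close copies that share reads uncertainly, fell from 32419 ± 7960 to 1555 ± 1248 and from 8187 ± 510 to 561 ± 568 (SD, n = 2). The list took 13.8% and 12.4% of reads in WT and 2.42% and 0.709% in the labelled double mutant, so the latter libraries differed from each other too. The list passed camera (adjusted p = 3.11e-08), and the adjusted p was 0.582 with an estimated correlation. The count of falling members was 5 with edgeR, 24 with DESeq2 and 18 with library size only. When WT replicate 1 or WT replicate 2 was left out, limma called 0, with 5 and 5 at an unadjusted p below 0.05 and 10 and 10 by edgeR; without labelled double mutant replicate 1 it called 16, at a median of -4.40, and without replicate 2 it called 4, at a median of -2.38.

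**Figure D4:**
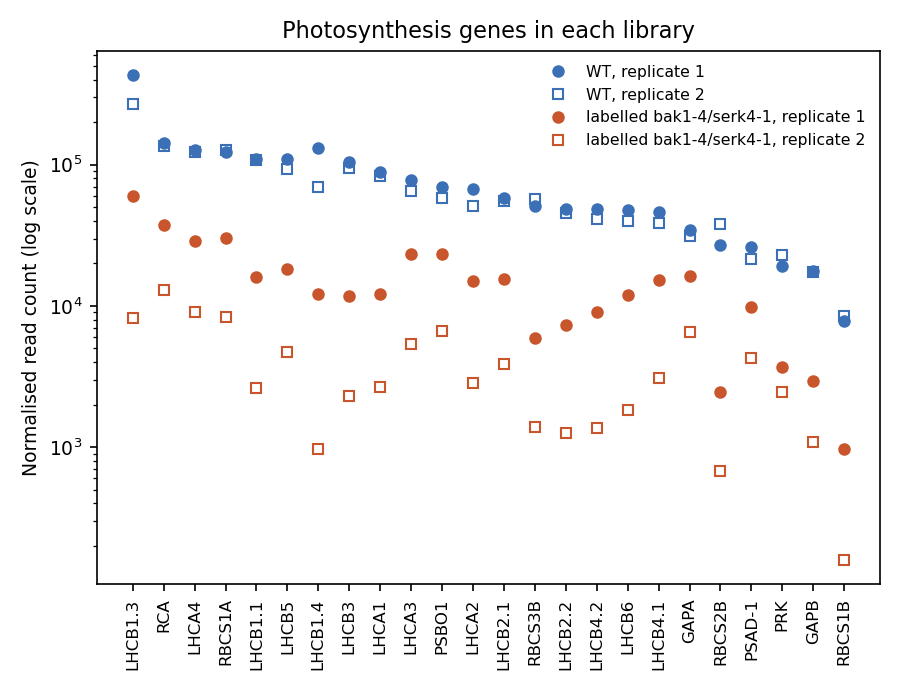
Normalised read counts (log scale) of the 24 photosynthesis genes in each library, ordered by the WT mean; filled circles are replicate 1 and open squares replicate 2. For RBCS1B the values were 7827 and 8548 in WT and 963 and 160 in the labelled double mutant.

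Senescence genes were higher. Of 14, 11 rose and 0 fell, and 12 rose when adjusted over the list alone, with a median log2 fold change of 2.65. SAG13 (AT2G29350) rose from 6.33 ± 0.305 to 10713 ± 1537 and BCB (AT5G20230), a blue copper-binding protein, from 253 ± 189 to 13284 ± 8017 (SD, n = 2). All 14 cell division genes had negative log2 fold changes, with a median of -0.98, but 1 fell and 13 did not pass, also when adjusted over the list alone. That gene was CYCD3;1 (AT4G34160), a D-type cyclin, which fell from 541 ± 79.3 to 106 ± 9.50. The senescence and cell division lists passed camera (adjusted p = 1.40e-07 and 6.21e-04), with an adjusted p of 0.225 and 0.365 with an estimated correlation. After WT replicate 1 or WT replicate 2 was left out, limma called 0 members of both lists, with 10 and 10 senescence genes higher and 1 and 1 cell division gene lower at an unadjusted p below 0.05, and 8 and 9, and 1 and 1, by edgeR. Without labelled double mutant replicate 1 limma called 5 senescence genes, and without replicate 2 it called 9 and did not call CYCD3;1.

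Brassinosteroids are steroid hormones whose receptor BRI1 signals with BAK1. Of 9 genes of their synthesis, 1 rose and 0 fell, also when adjusted over the list alone. BR6OX2 (AT3G30180), which catalyses the last steps, rose from 305 ± 55.5 to 2397 ± 1638 (SD, n = 2). Of 15 genes of signalling and growth, 4 rose and 6 fell, also when adjusted over the list alone. The receptor gene BRL3 (AT3G13380) rose from 210 ± 40.7 to 1802 ± 353 and XTH24 (AT4G30270), a cell wall enzyme, from 5430 ± 2880 to 35694 ± 5515, whereas the expansin gene EXPA8 (AT2G40610) fell from 1214 ± 99.3 to 41.0 ± 50.3. BRI1 (AT4G39400), chosen after its values were seen, had a log2 fold change of 0.06 (SE 0.32) and did not pass. Neither list passed camera (adjusted p = 0.718 and 0.403). Without WT replicate 1 and without WT replicate 2, limma called 0 members of both lists, with 1 and 1 synthesis gene and 3 and 4 signalling genes higher and 5 and 4 signalling genes lower at an unadjusted p below 0.05, and 1 and 1, 2 and 3, and 5 and 4 by edgeR. Without labelled double mutant replicate 1 and without replicate 2, limma called 1 and 0 synthesis genes higher and 1 and 1 signalling gene higher with 4 and 2 lower.

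Because the series concerns protein glycosylation, genes of the endoplasmic reticulum were listed separately. Of the 7 oligosaccharyltransferase subunits, which attach N-glycans to proteins, limma called 0, also when adjusted over the list alone. There were 0 at an unadjusted p below 0.05, and edgeR called 0. All 7 log2 fold changes were positive, from 0.04 to 0.72. HAP6 (AT4G21150), the subunit with the highest mean, had 1759 ± 305 in WT and 2321 ± 486 in the labelled double mutant (SD, n = 2; log2 fold change 0.39, SE 0.33). Of 17 genes of folding and quality control, 4 rose and 0 fell, and 6 rose when adjusted over the list alone. BIP3 (AT1G09080), a luminal chaperone, had 147 and 326 against 0.818 and 1.36 in WT, a ratio of 188 with a 95% counting interval of 63.9 to 917. CRT3 (AT1G08450), a calreticulin used by immune receptors, rose from 661 ± 86.6 to 4052 ± 227. The oligosaccharyltransferase list did not pass camera (adjusted p = 0.311), except without labelled double mutant replicate 2 (0.0433). The folding list did (adjusted p = 8.35e-05, and 0.353 with an estimated correlation). With WT replicate 1 or WT replicate 2 left out, limma called 0 folding genes, with 4 and 3 at an unadjusted p below 0.05 and 2 and 2 by edgeR; without labelled double mutant replicate 1 it called 2.

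Of 15 oxidative stress genes, 6 rose and 0 fell, and 7 rose and 1 fell when adjusted over the list alone. The zinc finger genes ZAT10 (AT1G27730) and ZAT12 (AT5G59820) rose from 75.0 ± 0.676 to 684 ± 273 and from 95.5 ± 32.1 to 776 ± 322 (SD, n = 2). Of 8 heat shock genes, 3 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone. HSP90.1 (AT5G52640), a chaperone, rose from 146 ± 4.44 to 713 ± 124. Of 9 low-oxygen genes, 1 rose, also when adjusted over the list alone: HB1 (AT2G16060), a haemoglobin, from 91.3 ± 16.9 to 362 ± 129. Of 14 genes of root tissue, 1 rose, also when adjusted over the list alone: FRD3 (AT3G08040), a citrate transporter, from 104 ± 20.5 to 405 ± 132. Of 11 circadian clock genes, limma called 0, also when adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p below 0.05 and 0 by edgeR. LHY (AT1G01060), a clock transcription factor, had 3726 and 8593 in WT and 2091 and 3942 in the labelled double mutant. The oxidative stress and heat shock lists passed camera (adjusted p = 0.0405 and 0.0461), with an adjusted p of 0.630 and 0.407 with an estimated correlation. The low-oxygen, root and clock lists did not (adjusted p = 0.161, 0.593 and 0.593).

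The heat shock call was lost without labelled double mutant replicate 1 (camera adjusted p = 0.0696) and replicate 2 (0.0781) and with edgeR (0.0753), and the oxidative stress call without labelled double mutant replicate 1 (0.285). When WT replicate 1 or WT replicate 2 was left out, limma called 0 members of these 5 lists, with 6 and 6 oxidative stress and 3 and 4 heat shock genes higher at an unadjusted p below 0.05 and 5 and 4, and 2 and 2, by edgeR; without labelled double mutant replicate 1 and without replicate 2 it called 2 and 3 oxidative stress and 1 and 0 heat shock genes, and neither HB1 nor FRD3.

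Genes beside the mutated loci were examined because an insertion can alter its neighbours. Among the 10 annotated genes on each side of BAK1, 18 were tested and 3 were called, close to the 18.9% called among all genes (two-sided Fisher's exact test p = 1). These were a peroxidase gene, AT4G33420, directly beside BAK1 (log2 fold change 1.75, SE 0.27), AT4G33467 (3.61, SE 0.83) and the histone deacetylase gene HDA14 (-2.33, SE 0.45), chosen after their values were seen. Among the genes around SERK4, 5 were tested and 2 were called (two-sided Fisher's exact test p = 0.240, adjusted p = 0.481 over both loci). They were SERK5 and ALD1 (AT2G13810), which acts in pipecolic acid synthesis and was chosen after its values were seen (log2 fold change 6.94, SE 0.85).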

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

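The edgeR test on recovered reads, TMM factors and thinning to the shallowest library were chosen only after the data were seen. The organelle alternative was not run, since the files hold 0 such loci. The values that answer a comparison include those of BAK1 and SERK4. BAK1 changed sign after thinning, and SERK4 was called with the replicate block, as given below. With no library left out, 359 of the 393 values that answer a comparison stayed the same. So did 701 of the 715 for the other 55 named genes, of which none reversed. For lists and genes, the same means an unchanged direction and side of the threshold. For counts of changed genes it means only a count near the main fit's. Changed genes numbered 3653 to 5226 under the alternatives without a block and with every library kept, and the median of all genes stayed within 0.10 of 0. The split of higher against lower calls was 53.1% higher, and 49.0% with library size only. With RLE factors 4265 of the 4268 calls were kept. The deposited values already carry DESeq size factors, which are of that kind, so limma with RLE factors nearly repeats the main fit. After thinning to 7414741 reads per library, limma called 4042 genes, 3843 of them among the original 4268. It lost 261 of the 1067 called genes with the lowest mean values and 16 of the 1067 with the highest.

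The heat shock list, at a median of 1.28, was no longer called with DESeq2 (1.54), edgeR with RLE factors (1.21), edgeR with TMM (1.19), a pseudocount of 0.1 (1.77), a stricter filter (0.37) or thinning (0.55). The heat shock list stayed called with a pseudocount of 5 (0.66). The oxidative stress list, at a median of 0.65, was no longer called after thinning (1.103). It stayed called at 1.06 with DESeq2, 1.13 and 1.11 with edgeR (RLE and TMM), 1.04 with a pseudocount of 0.1 and 1.76 with the stricter filter. The low-oxygen list was called under the stricter filter (1.00). BAK1, and with it the SERK list whose median it is, turned from -0.00 to 0.060 after thinning; neither value was called. Medians over fewer members are not directly comparable, and no cause was tested.

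With an estimated correlation, camera called 0 of the 21 lists, with 4 at an unadjusted p below 0.05, while fry called 11. The medians are the same values as before: CRK 2.88, salicylic acid 5.33, ethylene 1.37, pattern-triggered immunity 1.77, intracellular receptors 1.61, folding 0.79, indolic compounds 3.42, aliphatic glucosinolates -2.81, photosynthesis -3.26, senescence 2.65, oxidative stress 0.65, cell division -0.98 and heat shock 1.28. In fry, aliphatic glucosinolates (-2.81), photosynthesis (-3.26) and oxidative stress (0.65) were not called, and the clock list was (0.27, adjusted p = 0.0471). The estimated correlation was 0.979 for photosynthesis, which widens that list's test by construction.

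The libraries share the numbers 1 and 2, and no label says that a number marks a shared batch or day. Differences between replicate 2 and replicate 1 in the WT and in the labelled double mutant correlated with r = 0.64 across 16780 genes, which are not independent. With the replicate block, limma called 9032 genes (4545 higher and 4487 lower, 7234 at least 2-fold), including all 4268 called without it. SERK4 was then called at 0.79 (adjusted p = 0.0339, against 0.190 without the block), as were SERK1 (-0.90, adjusted p = 0.0348) and LHY (-0.98, adjusted p = 0.0394), and the oxidative stress (0.65) and heat shock (1.28) lists were not. Lower members numbered 11 in cell division against 1 without the block, 17 against 8 in photosynthesis and 8 against 3 in aliphatic glucosinolates. The clock list had 3 higher and 3 lower against 0 of both, jasmonate 10 and 5 against 4 and 1, low oxygen 5 and 1 against 1 and 0, folding 9 higher against 4, and oligosaccharyltransferase 1 higher against 0.

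Leaving out 1 library leaves a single library in an arm, which is then assumed to vary like the other group. Over the 4 such fits, limma called 0 to 1998 genes (0 to 941 higher, 0 to 1057 lower, 0 to 1998 at least 2-fold), with 4047 to 7941 at an unadjusted p below 0.05, while edgeR called 3123 to 4903. Without a WT library the spread comes from the labelled double mutant pair. Why limma (log2 values) and edgeR (reads) differed in these fits was not tested. BAK1 and the SERK list ran from -0.17 to 0.17, heat shock from 1.21 to 1.49, oxidative stress from 0.47 to 1.37, oligosaccharyltransferase from 0.15 to 0.58, aliphatic glucosinolates from -4.27 to -1.04 and photosynthesis from -4.40 to -2.38. Of the 208 values of the 52 called named genes in these fits, 75 kept the call and 133 lost it.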

Other observations

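Families formed from product names were tested without a prior choice of family, and their named genes were chosen after their values were seen. Of 346 families, 54 passed camera with the preset correlation, 27 higher and 27 lower in the labelled double mutant. With an estimated correlation 0 passed (lowest camera adjusted p = 0.983), with 5 at an unadjusted p below 0.05. That form has few degrees of freedom with so few libraries, so its 0 does not decide whether correlation explains the preset calls. The product names split the WRKY transcription factors, regulators of defence: of 52 under the name of DNA-binding proteins 27 rose and 1 fell (camera adjusted p = 1.95e-09), and of 11 under another name 5 rose and 1 fell, which did not pass (0.165). Among the former WRKY46 had a log2 fold change of 6.19 (SE 0.49) and WRKY51 5.53 (SE 0.47). Of 83 TIR-NBS-LRR receptor genes 21 rose and 1 fell. The NAC transcription factors are split likewise: of 66 under the commoner name 24 rose and 0 fell, among them NAC019 (5.94, SE 0.39), and of 13 under another name 3 rose and 2 fell, which did not pass (camera adjusted p = 0.404). Of 20 berberine bridge enzyme-like genes 12 rose and 2 fell, led by AT1G26390 (8.63, SE 0.54) and AT1G26410 (7.77, SE 0.44). Of 14 genes of the copper transport family 9 rose and 0 fell, and the highest were AT5G52760 (8.57, SE 0.42) and AT5G52720 (8.10, SE 0.42). Under the separate name of heavy metal transport/detoxification, 8 of 41 genes rose and 4 fell, which did not pass (camera adjusted p = 0.752).

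In other families that passed camera with the preset correlation, and not with an estimated one, more members fell than rose. Of 64 SAUR genes, which respond to auxin, 28 fell and 5 rose, and AT1G29500 had 0 reads in the labelled double mutant and was at least 39.3-fold lower, with a bound of 13.8-fold without replicate 1 and 25.6-fold without replicate 2. Of 59 pectin lyase-like genes 20 fell and 3 rose, led by AT1G10640 (-6.18, SE 0.90). Of 13 fatty acid desaturase genes 8 fell and 0 rose, among them FAD8 (-3.85, SE 0.45), which makes trienoic fatty acids in plastids. Of 30 phototropic-responsive NPH3 family genes 12 fell and 0 rose. Without either WT library limma called 0 genes at all, and edgeR called 3123 and 3226.

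The tests on the hour of harvest, on whole-gene counting, on scaling, on the depth of labelled double mutant replicate 2 and on green tissue, below, were chosen only after the results they bear on were seen.

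Replicate 1 and replicate 2 differed from each other in the same way in both genotypes. The correlation across genes stayed at 0.612 after thinning to equal depth and at 0.561 after regression on spliced length and GC content, which argues against depth and against these properties as the whole cause. A candidate explanation is another hour of the day at harvest: all 11 clock genes differed between the replicates in the same direction in both genotypes, CCA1 by 1.56 and 1.53 and PRR5 by -1.67 and -1.79 on the log2 scale in WT and in the labelled double mutant. Their median shared difference lay at percentile 100 of 10000 random lists matched on mean value, 0.93 against a median of 0.19. A batch of another kind stays open, and no label gives an hour or a batch.

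BAK1 and SERK4 reads were not lower in the libraries labelled double mutant. For BAK1, the windows argue against reads of near-identical genes, since 2.63% of its 50-base windows matched another locus. For SERK4 the share was 35.1%, 845 of 860 such windows with SERK5, and reads of SERK5 may add to its count; this cannot be told apart here without the reads. Transcripts of disrupted genes counted over the whole gene also stay open: BAK1 stood at 99.3% of WT, and counts per gene do not show where reads fall. A wrong label was not tested.

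Photosynthesis genes were lower in the labelled double mutant. A scaling factor moves all genes of a library alike, so scaling is argued against by the list's median minus that of all other genes (-3.216). Its 95% bootstrap interval, from -3.90 to -2.82, resamples genes within the same libraries and measures no spread between libraries. The list's median was -4.40 without labelled double mutant replicate 1 and -2.38 without replicate 2. The latter value argues against the shallow depth of replicate 2. A smaller share of green tissue would raise root genes. The root list's median was -0.29, with a 95% bootstrap interval, also over genes only, from -0.56 to 0.17. The share of green tissue can therefore not be told apart from lower expression per cell. The genotype remains an open, untested biological explanation.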
